A study of Mus musculus with 9 samples.

How the data were processed

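miRNAs were measured by small RNA sequencing in 9 colon samples of C57BL/6J mice, 3 each of Control, DSS and DSS_RJA. Per the labels' protocols, adaptors were ligated to small RNA with an NEBNext small RNA kit, the product was amplified by PCR, and inserts of 18 to 40 bp were sequenced as single reads of 50 bases. The submitters' processing notes name Bowtie and DESeq, without a version or a role. The genome build, the miRNA annotation and the rules for reads that match several miRNAs are not given in the sources used here. The authors deposited raw read counts per mature miRNA, 1 column per sample, per the file headers. The authors also deposited TPM values. Each deposited TPM equalled the count divided by the sample total and scaled so that each sample sums to 1000000, with a largest difference of 4.66e-10 and no term for length.

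The table held 1155 entries, 1126 with mouse miRNA names and 29 that the authors numbered themselves. Samples were grouped by their labels. Library totals were 5985153 to 8280980 counts, and miR-143-3p took about 70% of them, so the depth for other miRNAs was lower than the totals show. Reads amplified by PCR without molecular identifiers are not independent molecules. The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. miRNAs were kept by filterByExpr with a minimum count of 10 (a CPM of 1.42 at the median library size in at least 3 samples), which left 433 of 1155. Library sizes were scaled by TMM, whose mean factors were 0.879 in Control, 1.14 in DSS and 1.01 in DSS_RJA. The quasi-likelihood test was fitted to all 9 samples with 1 mean per group and no covariate, so that the 3 comparisons shared 6 residual degrees of freedom. p-values were adjusted by the Benjamini-Hochberg method over the 433 miRNAs, at a threshold of 0.05. CPM values use the TMM-scaled library sizes and are given as mean ± SD. Standard errors of log2 fold changes were taken as the size of the fold change divided by the square root of the F statistic, which is approximate. With 3 samples against 3, an exact permutation test of a single miRNA cannot give a p under 0.1, so none is reported.

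In all, 18 lists of miRNAs were fixed before the data were examined: colon epithelium, smooth muscle, skeletal muscle, myeloid and pan-leukocyte, lymphocyte, erythrocyte, endothelium, neurons and neuroendocrine, fibroblast and mesenchyme, inflammation-responsive, reported to target Nlrp3, miR-210, the miR-17 family clusters, let-7, miR-29, miR-30, the miR-34 and miR-449 family and the Dlk1-Dio3 imprinted cluster. No member of the epithelial list was in another list, against 2 of the 6 lymphocyte and 2 of the 12 inflammation-responsive members, 1 of the 4 myeloid members and 4 of the 5 in the Nlrp3 list. The miR-210 list was taken from the title of the series. The miRNAs in these lists can also be expressed by other cells of the colon. Of the lists, 13 had at least 3 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. None of the list calls in any of the 3 comparisons held with an estimated correlation. fry was run beside it. It tests whether a list's members move, on balance, 1 way, without reference to other miRNAs. Its adjusted p was under 0.05 for lymphocyte (0.0263), neurons (0.0263) and inflammation-responsive (0.0263) in DSS against Control, and for let-7 (0.0108), neurons (0.0208) and lymphocyte (0.0229) in DSS_RJA against DSS. For the epithelial list it was 0.0592 in DSS against Control, 0.384 in DSS_RJA against DSS and 0.515 in DSS_RJA against Control.

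The rule for the miRNAs named in the text was also fixed before the data were examined. In each comparison it took both arms of miR-210, and the 10 largest changes in each direction among called miRNAs with groups that did not overlap and a mean of at least 10 CPM. Where none passed in a direction it took the 3 with the smallest p. It also took the 5 most abundant miRNAs and up to 4 members of each list, the 2 with the smallest p and the 2 most abundant. miR-10a-5p, the fifth most abundant miRNA, had log2 fold changes of 0.23 ± 0.23, -0.43 ± 0.24 and -0.19 ± 0.23 in the 3 comparisons. Called miRNAs under 10 CPM, and list members named for comparison, were chosen after their values were seen. Positions and neighbouring genes of precursors come from the GENCODE M21 annotation of GRCm38, and the authors' own build is not given in the sources used here.

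Replicates were compared before averaging. The closest pair, Control 1 and Control 2, differed by 41.9 times sampling noise (chi-square per degree of freedom). This covers counting error only, so it shows that no pair of columns agreed within sampling noise, not that the samples were prepared from separate animals. Comparisons that share libraries were set against 100 simulations of unchanged groups, and the simulated counts of signs and smaller changes were added after the observed counts were seen. The tests were tested on counts simulated from the real means, in which 200 miRNAs were changed. In the simulation of DSS against Control, with 416 miRNAs, 63.4% of 2-fold and 96.2% of 4-fold changes were recovered and 2.59% of calls were false. For DSS_RJA against DSS, with 421 miRNAs, these were 62.9%, 95.6% and 2.58%, and for DSS_RJA against Control, with 421 miRNAs, 62.1%, 96.0% and 2.54%. Both kinds of simulation drew each miRNA independently, with the same dispersion in all groups. In the real data the mean log2 CPM of the epithelial miRNAs had an SD of 0.13 in Control, 1.04 in DSS and 1.68 in DSS_RJA. Changing 200 miRNAs also makes the adjusted threshold easier to pass, so these shares need not hold for the real samples.

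Alternatives tried were RLE scaling, library size only, no low-count filter, a filter of 10 CPM in 3 samples, DESeq2 1.42.0, limma-voom, fits with only the groups compared, the replicate number as a block, the 5 most abundant miRNAs left out, known miRNAs only, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), other thresholds, and leaving out each library. An epithelial score (the mean log2 CPM of the 10 epithelial miRNAs) as a covariate, and 1 miRNA kept of each set with near-identical counts, were added after the data were seen. The labels give no sequencing batch or date, so no values within batches are given.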

Results

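Small RNAs from the colon of C57BL/6J mice were sequenced to measure mature microRNAs (miRNAs), short RNAs that lower the output of their target messenger RNAs. The Control group had normal food and water. The DSS group was given 2.5% dextran sulfate sodium (DSS) to drink, a sulfated polysaccharide that injures the colon lining and is used to induce colitis in mice. The DSS_RJA group had DSS water together with royal jelly acid (RJA), 10 mg/kg in 0.2 mL by gavage each day. Each group held 3 samples, 9 in all, and total counts ranged from 5985153 (DSS_RJA 1) to 8280980 (Control 2) per library. The table listed 1155 miRNAs, of which 433 passed the low-count filter and were tested. These held 99.99% of all counts. The labels give each sample as a separate colon sample without naming its animal, so the p-values measure the spread between these samples.

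A single miRNA, miR-143-3p, which is abundant in smooth muscle, took 68.9% ± 2.30 of the counts in Control, 70.3% ± 4.53 in DSS and 70.5% ± 1.61 in DSS_RJA (SD, n = 3). miR-21a-5p, an abundant miRNA of many tissues, took 7.87% ± 1.46 in Control, 10.9% ± 3.42 in DSS and 10.3% ± 2.72 in DSS_RJA. The 3 Control libraries resembled each other most, with Spearman correlations across miRNAs of 0.982 to 0.987. The correlations were 0.960 to 0.967 within DSS and 0.941 to 0.972 within DSS_RJA, where DSS_RJA 1 and DSS_RJA 3 were the least alike pair. On the first principal component, which held 56.8% of the variance, Control libraries lay between 7.94 and 9.51 and DSS libraries between -14.4 and -3.04. The DSS_RJA libraries spread from -10.3 to 9.31.

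The first comparison asked which colon miRNAs differed between mice given DSS and untreated mice. In DSS colon, 10 miRNAs rose and 7 fell among the 433 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The strongest rises were in the miR-212/132 cluster, whose transcription responds to CREB. miR-212-3p rose 7.64-fold, from 2.62 ± 0.183 to 20.2 ± 10.5 CPM (counts per 1000000; SD, n = 3; adjusted p = 0.00585), and miR-132-3p rose 4.67-fold, from 23.8 ± 2.08 to 111.1 ± 44.1 CPM (adjusted p = 0.0119). miR-146a-5p, which is induced by NF-κB and restrains its signalling, rose 2.40-fold, from 793 ± 63.5 to 1900 ± 442 CPM (adjusted p = 0.00762). The largest fall was that of miR-194-1-3p, the 3p arm of a precursor of the intestinal miR-194, which was 21.9-fold lower in DSS, at 1.22 ± 0.877 CPM against 26.7 ± 3.19 (adjusted p = 0.00585). It rested on 2, 14 and 13 reads in the DSS libraries, against 185, 172 and 176 in Control, so the size of the fold is uncertain. The abundant arm, miR-194-5p, with a mean of 3344 CPM, had a log2 fold change of -2.45 ± 0.78 (standard error) that did not pass (edgeR adjusted p = 0.0749).

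The other rises were in miR-132-5p (log2 fold change 1.80 ± 0.41, standard error), miR-342-3p (1.61 ± 0.34), miR-129-2-3p (1.05 ± 0.23), miR-129-5p (0.76 ± 0.15) and miR-129b-3p (0.76 ± 0.15). The counts of miR-129-5p and miR-129b-3p differed by at most 2% in every library, so these are uncertain as separate calls. With 1 miRNA kept of each set with near-identical counts, 9 rose and 6 fell. The other falls were in miR-148a-5p (-2.06 ± 0.30), miR-3081-3p (-1.36 ± 0.23), miR-378c (-1.22 ± 0.28), miR-30e-5p (-1.13 ± 0.25) and miR-181d-5p (-0.88 ± 0.21). The rules for reads that match several miRNAs are not given. The call of miR-378c is therefore uncertain as separate from the more abundant miR-378a-3p of its family. Of the scarcer miRNAs, with a mean under 10 CPM, miR-212-5p (1.63) and miR-129-1-3p (1.05) rose and miR-200c-5p (-2.58) fell. The rises thus include both arms of miR-212 and miR-132, whose precursors lie in the same host transcript, and several miR-129 entries. They are therefore not independent of each other. In each of the 17, all 3 DSS libraries lay on the same side of all 3 Control libraries. Of the 433 tested miRNAs, 180 (41.6%) had groups that did not overlap, where chance gives 10% on average. The numbers were 57 (13.2%) for DSS_RJA against DSS and 94 (21.7%) for DSS_RJA against Control. Since miRNAs vary together, chance can put a single grouping far from that average.

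In the GENCODE M21 annotation of GRCm38, Mir212 (75173388 to 75173478) and Mir132 (75173682 to 75173747) lay on the plus strand of chromosome 11, in an intron of the noncoding transcript 1700016P03Rik. Mir194-1 lay on chromosome 1, from 185313319 to 185313385, on the plus strand, in an intron of the antisense transcript 2010103J01Rik on the same strand and opposite to an intron of Iars2. Mir146, the precursor of miR-146a-5p, lay on chromosome 11 from 43374397 to 43374461 outside other genes. Mir148a lay on chromosome 6 from 51269812 to 51269910, also outside other genes. Mir342 lay in an intron of Evl on chromosome 12, from 108658620 to 108658718, and Mir30e in an intron of Nfyc on chromosome 4, from 120772606 to 120772697.

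**Figure D1:**
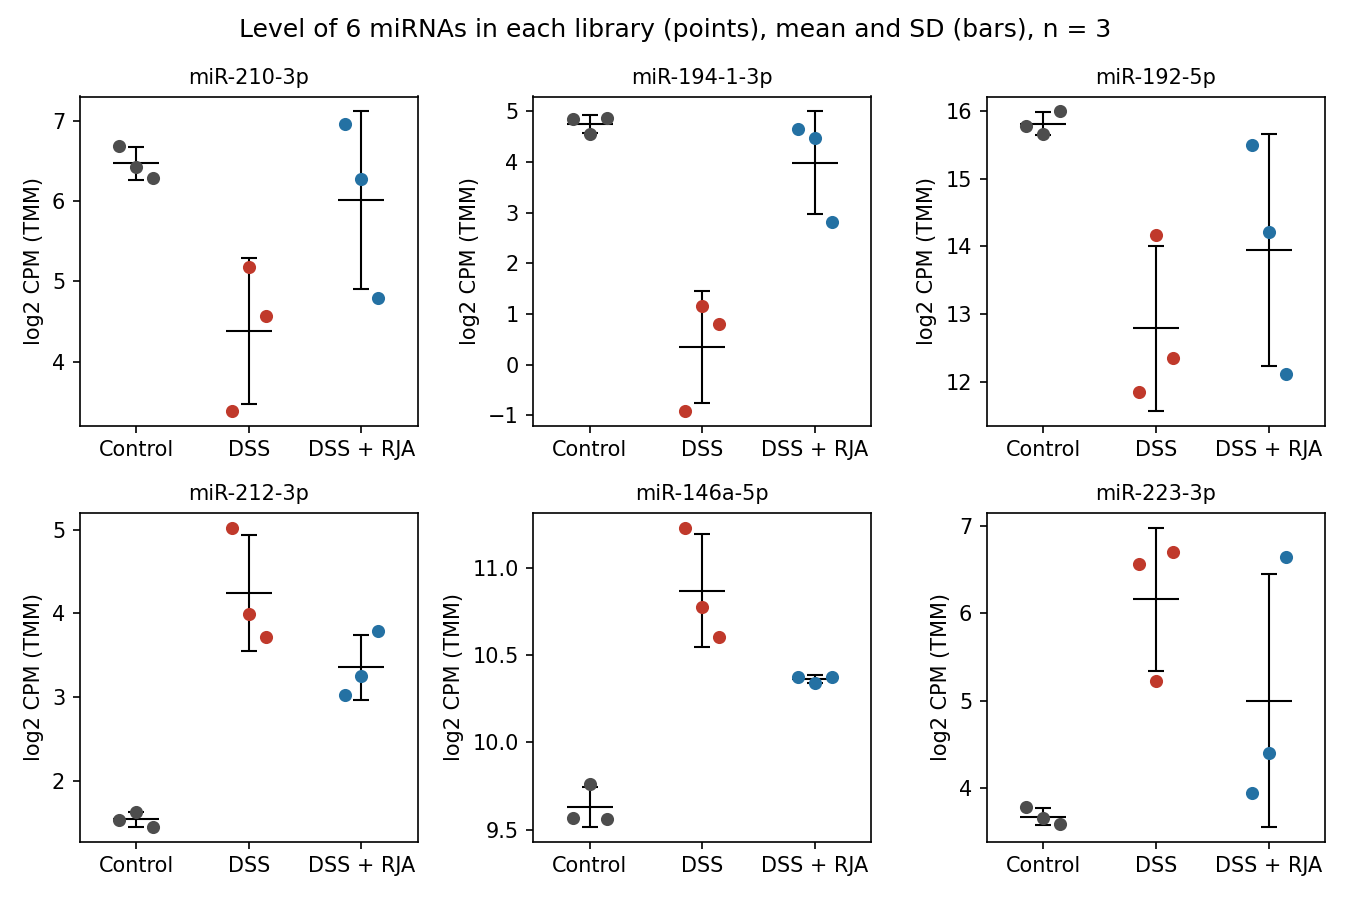
Level of 6 miRNAs in each of the 9 libraries, as log2 CPM after TMM scaling; points are libraries, the long bar is the group mean and the whiskers are the SD (n = 3). The 3 DSS libraries lie below the 3 Control libraries for miR-210-3p, miR-194-1-3p and miR-192-5p and above them for miR-212-3p, miR-146a-5p and miR-223-3p.

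The title of the series names miR-210-3p, the main miRNA induced by hypoxia. Its level was 23.2 ± 13.0 CPM in DSS and 89.0 ± 13.0 CPM in Control (SD, n = 3), a log2 fold change of -1.94 ± 0.54 (standard error) with an adjusted p of 0.0671, which did not pass. The reads behind these levels were 83, 259 and 210 in the DSS libraries and 673, 642 and 476 in the Control libraries, and the 2 groups did not overlap. The other arm, miR-210-5p, was at 4.85 ± 2.73 CPM in DSS and 12.3 ± 1.06 CPM in Control (adjusted p = 0.109). Adjusted over the list alone, both arms were lower in DSS. That list holds only the 2 arms and was taken from the title. The title may rest on these same data, so the list-alone result is not independent support. With a pair of groups in the fit in place of all 3, or with DESeq2, miR-210-3p passed, with log2 fold changes of -1.92 and -1.91. The fit to all 9 samples pools the spread of the 3 groups, so DSS_RJA also enters the standard error of this comparison. That error was 0.54 with all 9 samples and 0.39 with only Control and DSS. Without DSS_RJA 1, DSS_RJA 2 or DSS_RJA 3 it was 0.49, 0.58 and 0.38. With the mean level of epithelial miRNAs as a covariate, an alternative chosen after the data were seen, the log2 fold change of miR-210-3p was -0.41 ± 0.33. Mir210 lay on the minus strand of chromosome 7, from 141221384 to 141221493, outside other genes.

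Among the miRNA lists fixed beforehand, the 10 miRNAs of colon epithelium were all lower in DSS, with a median log2 fold change of -2.42. The camera test of the list gave an adjusted p of 9.44e-06, and adjusted p = 0.478 with an estimated correlation. The fry test gave an adjusted p of 0.0592. None of the 10 passed over all miRNAs tested, and 8 fell when adjusted over the list alone. miR-192-5p was at 9079 ± 8042 CPM in DSS and 57780 ± 6823 in Control, and miR-200b-3p, of the family that maintains the epithelial state, was at 3395 ± 3036 and 17738 ± 1166 CPM. miR-429-3p (-2.50 ± 0.75) and miR-141-3p (-2.52 ± 0.67) of the same family gave similar values. The mean log2 CPM of the 10 epithelial miRNAs was 11.57 ± 0.13 in Control and 9.12 ± 1.04 in DSS, where it was 8.32, 10.29 and 8.74 in DSS 1, DSS 2 and DSS 3.

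The 10 tested miRNAs of the inflammation-responsive list all had higher values in DSS, with a median log2 fold change of 1.49 (camera adjusted p = 6.77e-06, and adjusted p = 0.263 with an estimated correlation). Of these, 3 rose over all miRNAs tested and 6 adjusted over the list alone. miR-21a-5p, at 0.11 ± 0.28, was among those that did not pass. The myeloid and pan-leukocyte list (4 tested) had a median of 1.58, with camera adjusted p = 0.0392, and adjusted p = 0.533 with an estimated correlation. No member passed over all miRNAs and 2 rose adjusted over the list alone. They were both arms of miR-223, a miRNA abundant in neutrophils, and miR-223-3p was at 78.3 ± 36.0 CPM in DSS and 12.5 ± 0.885 in Control. The lymphocyte list (6 tested) had a median of 0.83, with camera adjusted p = 0.0392, and adjusted p = 0.263 with an estimated correlation. Its member miR-342-3p rose over all miRNAs, and 3 members rose adjusted over the list alone. miR-155-5p was at 1.72 ± 0.45, miR-150-5p at 1.51 ± 0.55 and miR-181a-5p at 0.15 ± 0.16. The Dlk1-Dio3 imprinted cluster (33 tested) had a median of 0.34, with 24 positive and 9 negative values and no member passing either way. Its camera adjusted p was 0.0392, and adjusted p = 0.552 with an estimated correlation.

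The neuron and neuroendocrine list (7 tested) had a median of 0.65 and the miR-17 family clusters (11 tested) a median of -0.44, with camera adjusted p of 0.0554 and 0.0747. Over all miRNAs miR-129-5p rose in the former and none changed in the latter. Adjusted over the list alone, 3 neuronal members rose and 4 members of the miR-17 clusters fell. The miR-30 family (5 tested) had a median of -0.42 with camera adjusted p = 0.0914, with miR-30e-5p lower over all miRNAs and 2 members lower adjusted over the list alone. Smooth muscle (7 tested, median -0.34, adjusted p = 0.278), fibroblast and mesenchyme (7 tested, median 0.30, adjusted p = 0.131), let-7 (9 tested, median 0.04, adjusted p = 0.319) and miR-29 (3 tested, median -0.01, adjusted p = 0.728) did not pass, and no member of them did, over all miRNAs or adjusted over the list alone. The list of miRNAs reported to target Nlrp3 (5 tested) had a median of -0.44 and a mean of 0.25, which differ in sign (adjusted p = 0.728). In it miR-30e-5p fell over all miRNAs, and 1 member rose and 2 fell adjusted over the list alone. Skeletal muscle, erythrocyte, endothelium and the miR-34 and miR-449 family had 2 tested members each, too few for camera, and medians of 0.02, -0.33, -0.08 and 0.30. No member of these 4 lists passed over all miRNAs or adjusted over the list alone.

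At an unadjusted p under 0.05 there were 143 miRNAs, 66 higher and 77 lower, where 21.65 would be expected by chance on average. Since miRNAs vary together, chance can also give numbers far from that average. The number of calls was 88 with only the Control and DSS libraries in the fit and 90 without DSS_RJA 3, and it was 3 without Control 1 or Control 3, 6 without Control 2, 5 without DSS 1, 46 without DSS 2 and 47 without DSS_RJA 1. With the mean level of epithelial miRNAs as a covariate, as above, 5 miRNAs were called and 13 of the 17 calls ended. Those kept were miR-212-3p (log2 fold change 2.19 ± 0.45), miR-146a-5p (1.14 ± 0.25), miR-194-1-3p (-2.98 ± 0.46) and miR-148a-5p (-1.34 ± 0.26). Over the 23 other fits miR-212-3p, miR-194-1-3p and miR-148a-5p were called in each, miR-146a-5p in 21, miR-132-3p in 19, miR-3081-3p in 18, miR-129-5p in 17, miR-132-5p, miR-342-3p and miR-129-2-3p in 16 each, miR-30e-5p in 15, miR-378c in 13 and miR-181d-5p in 10. miR-129b-3p was called in 16 of 22 fits, and the 3 called miRNAs under 10 CPM were not followed. Scaling by library size alone moved the median log2 fold change of all tested miRNAs from 0.01 to 0.39 and the calls from 10 higher and 7 lower to 64 higher and 9 lower, and turned that of miR-143-3p from -0.34 to 0.03.

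**Figure D2:**
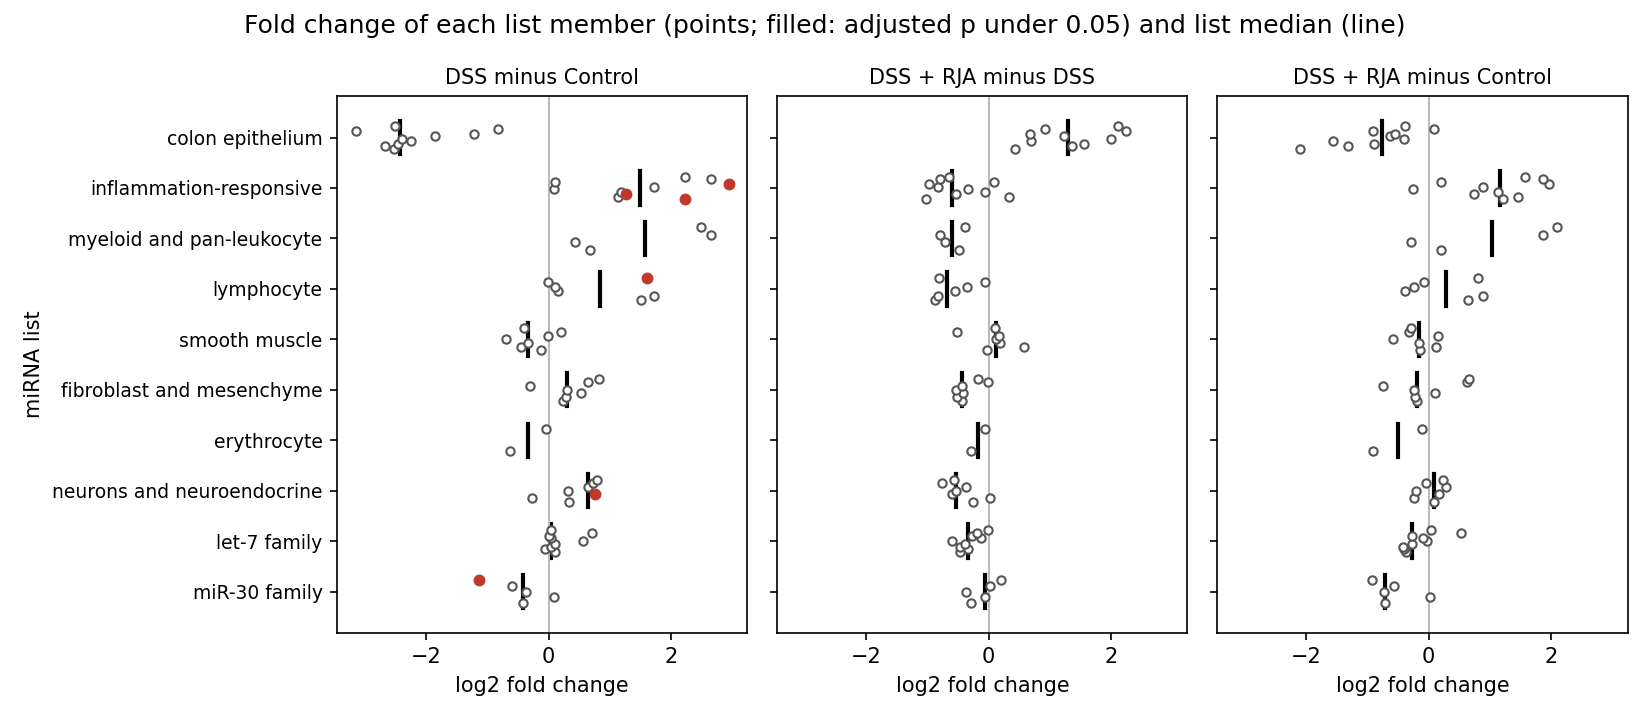
Log2 fold change of each tested member of 10 miRNA lists (points, filled where the adjusted p over all miRNAs was under 0.05) and the list median (line), in each of the 3 comparisons. The 10 epithelial miRNAs lie below 0 for DSS minus Control, with a median of -2.42, and above 0 for DSS_RJA minus DSS, with a median of 1.29.

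The second comparison asked which miRNAs differed when RJA was given with DSS. No gavage is recorded for the Control and DSS groups, so in this and the next comparison RJA cannot be told apart from gavage. Of the 433 miRNAs, 1 rose and none fell in DSS_RJA relative to DSS (edgeR). It was miR-194-1-3p, at 17.9 ± 9.76 CPM in DSS_RJA and 1.22 ± 0.877 CPM in DSS (SD, n = 3), 14.7-fold higher with an adjusted p of 0.0389, and all 3 DSS_RJA libraries lay above all 3 DSS libraries. This rested on 133, 145 and 44 reads in DSS_RJA against 2, 14 and 13 in DSS, so the size of the fold is uncertain. miR-210-3p was at 76.4 ± 48.4 CPM in DSS_RJA and 23.2 ± 13.0 in DSS, a log2 fold change of 1.72 ± 0.54 that did not pass (adjusted p = 0.186). Its reads were 663, 510 and 179 in the DSS_RJA libraries, and the groups overlapped. miR-210-5p had a log2 fold change of 1.67 ± 0.51 (adjusted p = 0.186). Adjusted over the list alone, which was taken from the series title as above, both arms were higher. In the same direction without passing were miR-18a-5p of the miR-17 clusters, at 7.04 ± 0.643 against 2.90 ± 0.289 CPM (adjusted p = 0.0617), and miR-106b-5p (0.94 ± 0.25, adjusted p = 0.138). The most abundant members of these clusters, miR-92a-3p and miR-25-3p, were at -0.05 ± 0.17 and -0.03 ± 0.17. Of the 11 tested members 6 were positive and 5 negative, with a median of 0.18 (camera adjusted p = 0.148).

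Among the miRNAs with negative values, the 3 with the smallest unadjusted p, none of which passed, were of the miR-129 group, enriched in neurons. The log2 fold changes were -0.59 ± 0.15 for miR-129-5p, -0.60 ± 0.15 for miR-129b-3p and -0.87 ± 0.23 for miR-129-2-3p, with adjusted p of 0.122, 0.122 and 0.125. The epithelial list had 10 positive values, with a median of 1.29 (camera adjusted p = 0.0081, and adjusted p = 0.574 with an estimated correlation). None of its members passed, over all miRNAs or adjusted over the list alone. miR-200b-3p was at 13482 ± 9894 CPM in DSS_RJA and 3395 ± 3036 in DSS. The mean log2 CPM of the epithelial miRNAs was 11.57, 10.66 and 8.32 in DSS_RJA 1, DSS_RJA 2 and DSS_RJA 3, a mean of 10.18 ± 1.68 against 9.12 ± 1.04 in DSS.

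Several lists were lower in DSS_RJA than in DSS by camera, each with adjusted p = 0.00792. They were lymphocyte (6 tested, median -0.67), inflammation-responsive (10 tested, median -0.59), neurons (7 tested, median -0.52) and let-7 (9 tested, median -0.34). With an estimated correlation these gave adjusted p of 0.131, 0.427, 0.131 and 0.152. Fibroblast and mesenchyme (7 tested, median -0.43) had camera adjusted p = 0.0197, and adjusted p = 0.427 with an estimated correlation. No member of these lists passed over all miRNAs, and 1 lymphocyte and 1 neuronal member fell adjusted over the list alone. Among the members, let-7e-5p had a log2 fold change of -0.59 ± 0.17, miR-181a-5p of -0.54 ± 0.16, miR-146a-5p of -0.53 ± 0.19 and miR-132-3p of -1.02 ± 0.36. The other 7 lists tested by camera did not pass, and 2 members of the miR-17 clusters rose adjusted over the list alone.

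At an unadjusted p under 0.05 there were 61 miRNAs, 37 higher and 24 lower. The log2 fold change of miR-194-1-3p was 2.91 to 4.30 over 23 other fits, and its call was kept in 11 of them. It was lost in the fits that left out any 1 library other than DSS_RJA 3, with limma-voom, with only the DSS and DSS_RJA libraries, with the replicate number as a block and on log2(TPM + 0.1), while the fit without DSS_RJA 3 gave 37 calls and miR-210-3p passed in it at 2.09.

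The third comparison asked what differed from untreated mice when RJA was given with DSS. No miRNA passed in edgeR, against 62 at an unadjusted p under 0.05 (37 higher, 25 lower), 2 with DESeq2 and 0 with limma-voom. The smallest adjusted p, 0.0982, was that of miR-1983, at 13.6 ± 4.41 CPM in DSS_RJA and 2.21 ± 1.03 in Control (SD, n = 3). miR-212-3p was at 10.2 ± 2.95 and 2.62 ± 0.183 CPM (adjusted p = 0.134), and miR-30c-5p at 477 ± 100.9 and 793 ± 22.9 CPM (adjusted p = 0.256). miR-210-3p was at 76.4 ± 48.4 CPM in DSS_RJA and 89.0 ± 13.0 in Control, a log2 fold change of -0.22 ± 0.52 (adjusted p = 0.87).

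By camera, the inflammation-responsive list was higher in DSS_RJA than in Control (median 1.16, adjusted p = 0.000516, and adjusted p = 0.687 with an estimated correlation), as was the Dlk1-Dio3 cluster (median 0.36, adjusted p = 0.0282, and adjusted p = 0.845 with an estimated correlation). The epithelial list was lower (median -0.76, adjusted p = 0.000618, and adjusted p = 0.735 with an estimated correlation), as was the miR-30 family (median -0.71, adjusted p = 0.00125, and adjusted p = 0.687 with an estimated correlation). Adjusted over the list alone, 4 inflammation-responsive miRNAs rose and 4 of the 5 miR-30 members fell. Among them miR-146a-5p had a log2 fold change of 0.73 ± 0.19 and miR-30e-5p of -0.93 ± 0.25. Both arms of miR-223 rose adjusted over the list alone, with miR-223-3p at 1.86 ± 0.67. Over all miRNAs neither passed (edgeR adjusted p = 0.268 for miR-223-3p and 0.256 for miR-223-5p), and the groups overlapped for miR-223-5p. miR-223-3p was at 15.2, 20.9 and 99.95 CPM in DSS_RJA 1, DSS_RJA 2 and DSS_RJA 3 and at 11.8 to 13.5 in Control. Most of its rise thus came from DSS_RJA 3. miR-451a, a miRNA of red blood cells, was at 69.6 ± 14.1 CPM against 130.8 ± 43.7 and fell adjusted over the list alone. The other 9 lists tested by camera did not pass. Adjusted over the list alone, 1 fibroblast member rose and 1 fell, as in the Nlrp3 list. The list of miRNAs reported to target Nlrp3 had a median of 0.13 and a mean of 0.26, while its camera direction was down. Without DSS_RJA 3 the epithelial list no longer passed (adjusted p = 0.245), nor did the Dlk1-Dio3 cluster (adjusted p = 0.942).

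The DSS changes were then set against those with RJA. All 17 miRNAs called in DSS against Control had the opposite sign in DSS_RJA against DSS, and all 17 had a smaller change in DSS_RJA against Control. These comparisons share libraries: in 100 simulations of unchanged groups, the 17 miRNAs with the smallest p in DSS against Control gave a mean of 14.99 opposite signs and 14.96 smaller changes, each with a central 95% range of 12 to 17. The counts of 17 lie within those ranges. Only 1 of them, miR-194-1-3p, passed in both comparisons with opposite signs. Independent lists would share 0.0162 and simulated unchanged groups gave a mean of 0.01, but the first leaves out the shared DSS libraries and the second the effects, so neither shows that 1 is more than sharing would give. The correlation of log2 fold changes across the 433 miRNAs was -0.772. Simulated unchanged groups sharing the DSS libraries gave a mean of -0.503, with a central 95% range of -0.591 to -0.386. The simulations drew each miRNA independently with the same dispersion in all groups, while the real DSS and DSS_RJA libraries varied more than Control. The simulated values may therefore understate what sharing alone gives. miRNAs are not independent replicates. The covariance was -0.446 against a simulated -0.0841, a difference of -0.362.

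Against the same Control libraries, DSS and DSS_RJA shared no called miRNA. Of the 17 DSS calls, 16 had the same sign in DSS_RJA against Control, where the same simulations gave a mean of 15.26 and a range of 13 to 17. The log2 fold changes correlated at 0.706 across miRNAs, against 0.493 in simulated unchanged groups, and the covariance was 0.366 against 0.0811, a difference of 0.285. Groups of 3 cannot be split into parts of 2 libraries, so part of the excess in both relations may come from the shared libraries.

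**Figure D3:**
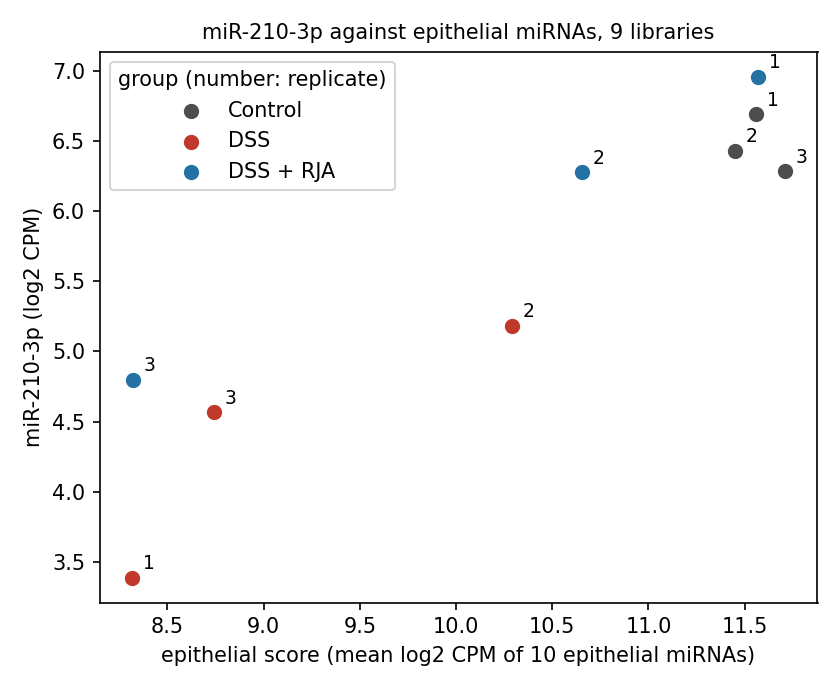
Level of miR-210-3p (log2 CPM, vertical axis) against the mean log2 CPM of 10 epithelial miRNAs (horizontal axis) in the 9 libraries, coloured by group and numbered by replicate. DSS_RJA 3 lies at 8.32 on the horizontal axis, beside DSS 1 at 8.32, and DSS_RJA 1 lies at 11.57, among the Control libraries.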

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

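All alternatives were fixed before the data were examined except the epithelial score as covariate and 1 miRNA kept per near-identical set. A further alternative, without DSS 2 and DSS_RJA 3 together, was run after the data were seen and dropped because it picked libraries by the measured outcome. No alternative reversed a call. The fit to all 9 samples pools the spread of the 3 groups, so leaving out a library or group also changes the spread used for the others. Beyond this, the causes of the changes below were not tested. With fewer libraries the fits also have fewer degrees of freedom.

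The 17 calls in DSS against Control became 73 with library size only, 73 with no low-count filter (30 higher, 43 lower), 28 with at least 10 CPM in 3 samples, 63 with DESeq2 (25 higher, 38 lower), 38 with limma-voom, 88 with 2 groups only, 29 with the 5 most abundant miRNAs left out, 86 on log2(TPM + 1) (65 higher, 21 lower), 78 on log2(TPM + 0.1) (63 higher, 15 lower), 5 with the epithelial score as covariate, 83 at an adjusted p of 0.10 and 143 at an unadjusted p of 0.05. Leaving out each library gave 3 to 90. Of the 17, all were among the calls of DESeq2, limma-voom and the fit with 2 groups, 15 among those with library size only and 4 among those with the covariate.

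The 1 call in DSS_RJA against DSS became 2 with RLE, 40 with no filter, 15 with DESeq2, 0 with limma-voom, 0 with 2 groups only, 2 with the 5 most abundant left out, 2 with known miRNAs only, 2 on log2(TPM + 1), 0 on log2(TPM + 0.1), 10 with the covariate, 4 at an adjusted p of 0.10 and 61 unadjusted. Leaving out each library gave 0 to 37, with 0 for every library except DSS_RJA 3. The 0 calls in DSS_RJA against Control became 19 with no filter, 2 with DESeq2, 2 with 2 groups only, 2 on log2(TPM + 0.1), 1 at an adjusted p of 0.10 and 62 unadjusted, and 0 to 1 on leaving out each library (1 without DSS 1 or DSS 2).

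The 1 miRNA called with opposite signs in DSS against Control and DSS_RJA against DSS became 2 with RLE, 30 with no filter, 11 with DESeq2, 0 with limma-voom, 0 with 2 groups only, 2 with the 5 most abundant left out, 2 with known miRNAs only, 2 on log2(TPM + 1), 0 on log2(TPM + 0.1), 3 with the covariate, 4 at an adjusted p of 0.10 and 45 unadjusted, and 0 to 31 on leaving out each library (31 without DSS_RJA 3, 0 for each other library). The 0 miRNAs called alike in DSS and DSS_RJA against Control became 16 with no filter, 1 with DESeq2, 1 with 2 groups only, 1 on log2(TPM + 0.1), 39 unadjusted, and 0 to 1 on leaving out each library (1 without DSS 1).

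The log2 fold change of miR-210-3p in DSS against Control passed with no filter (-1.92), DESeq2 (-1.91), limma-voom (-2.11), 2 groups only (-1.92) and log2(TPM + 1) (-1.69), and was -2.36 to -1.57 on leaving out each library, passing without DSS 2, DSS_RJA 1 or DSS_RJA 3. In DSS_RJA against DSS it passed with no filter (1.68) and DESeq2 (1.67), and was 1.17 to 2.13 on leaving out each library, passing without DSS_RJA 3. In DSS_RJA against Control it passed in none, was 0.46 with the covariate and -0.72 to 0.19 on leaving out each library.

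No pairing of the samples by replicate number was seen. Deviations from group means of libraries with the same number correlated at -0.457 to 0.183. With 3 libraries per group this check cannot exclude a pairing. With the replicate block there were 4, 0 and 0 calls in DSS against Control, DSS_RJA against DSS and DSS_RJA against Control and 0 called with opposite signs, and miR-210-3p was at -1.93, 1.59 and -0.33.

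The lists were run under 14 of the alternatives. Over these the 15 list calls were lost 48 times: 15 with an estimated correlation, 10 with fry, 4 with library size only and 19 on leaving out 1 library. With library size only the adjusted p were 0.125 (myeloid and pan-leukocyte), 0.0594 (lymphocyte) and 0.0757 (Dlk1-Dio3) in DSS against Control and 0.0557 (Dlk1-Dio3) in DSS_RJA against Control. On leaving out 1 library, the losses in DSS against Control were myeloid and pan-leukocyte (adjusted p = 0.0787 without Control 1, 0.0543 without Control 2, 0.0889 without DSS 1), lymphocyte (0.0787 without Control 1, 0.0555 without DSS 1, 0.0543 without DSS_RJA 3) and Dlk1-Dio3 (0.0505 without Control 3, 0.0889 without DSS 1). In DSS_RJA against DSS they were epithelium (0.0958 without DSS 1, 0.0666 without DSS 3, 0.366 without DSS_RJA 1), fibroblast (0.0846 without DSS 1, 0.0902 without DSS_RJA 1, 0.0812 without DSS_RJA 2) and inflammation-responsive (0.0846 without DSS 1, 0.120 without DSS_RJA 1). In DSS_RJA against Control they were epithelium (0.245 without DSS_RJA 3) and Dlk1-Dio3 (0.0869 without Control 3, 0.942 without DSS_RJA 3).

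Over up to 23 alternatives, the 166 named miRNA values gave 3323 results on the same side of the threshold with the same direction, 187 that newly passed, 87 that no longer passed and 186 uncalled values that moved. The 39 list tests over 14 alternatives gave 464, 7, 48 and 27. Depth limits the miRNAs outside the 433 tested.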

Other observations

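The splits of the samples were planned. The tests of the epithelial score, the scaling, the leukocyte and smooth muscle scores and the exchanged labels were chosen after the results were seen, as were the miRNAs named in the next paragraph.

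The miR-183/96/182 cluster, which is transcribed as a unit and best known from sensory organs, was outside the fixed lists. miR-182-5p was at 591 ± 345 CPM in DSS and 2504 ± 104 CPM in Control (SD, n = 3), miR-183-5p at 274 ± 169 and 1063 ± 15.2, and miR-96-5p at 52.4 ± 24.8 and 197.9 ± 5.43. The edgeR adjusted p of these were 0.0735, 0.0749 and 0.0554, so none passed, though the groups did not overlap for any of the 3. In DSS_RJA the same miRNAs were at 1775 ± 1251, 859 ± 567 and 140.4 ± 84.2 CPM. miR-205-5p, a miRNA of stratified epithelia, was at 3.43 ± 1.80 CPM in DSS, 31.6 ± 3.44 in Control and 11.3 ± 11.3 in DSS_RJA (adjusted p = 0.0554 for DSS against Control). The abundant arm of the called miR-148a-5p, miR-148a-3p, was at 4934 ± 2036 CPM in DSS and 13810 ± 1366 in Control (adjusted p = 0.0735). miR-378a-3p, of the family of the called miR-378c, was at 5646 ± 1350 and 12432 ± 950 CPM (adjusted p = 0.0661).

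Over 111 precursors with both arms tested, the log2 fold changes of the arms had the same sign in 91 (82.0%) for DSS against Control, 84 (75.7%) for DSS_RJA against DSS and 72 (64.9%) for DSS_RJA against Control. The correlations across precursors were 0.870, 0.702 and 0.542, and miRNAs are not independent replicates. In 12 pairs of tested miRNAs the counts differed by at most 2% or 1 count in every library, among them miR-24-3p with miR-3074-5p and miR-1a-3p with miR-1b-5p. Of the 9 such pairs with both precursors annotated, 7 had precursors that overlapped on opposite strands. A test of that share, with limits set in advance, was dropped after the count fell between the limits.

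miR-210-3p had a log2 fold change of -1.94 ± 0.54 (standard error) in DSS against Control. The scaling between libraries is argued against as its cause, since the smallest change over the 3 scalings was -1.57 ± 0.51, with library size only. A lower share of epithelial RNA in the DSS libraries is a candidate explanation: with the epithelial score as covariate the change was -0.41 ± 0.33. With group means removed, miR-210-3p followed the score over the 9 libraries (Pearson r = 0.934, one-sided exact permutation p = 0.0185 over 216 arrangements; Spearman rho = 0.883, p = 0.0324), with r = 0.843 without DSS_RJA 1 and DSS_RJA 3, but not within Control, where scores of 11.45, 11.56 and 11.71 went with log2 CPM of 6.43, 6.69 and 6.29. The mean log2 CPM of the 4 myeloid and pan-leukocyte miRNAs fell as miR-210-3p rose within each group. In Control it was 3.58, 3.54 and 3.73 in Control 2, Control 1 and Control 3. The relation therefore cannot tell a lower epithelial share apart from more leukocyte RNA or another change that varies with both. A change of miR-210-3p inside epithelial cells stays open, since the epithelial score differs between the groups too, and in DSS_RJA against DSS the value with the covariate was 0.87 ± 0.25 (edgeR adjusted p = 0.103).

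In DSS against Control all 10 miRNAs of the epithelial list had negative and all 4 of the myeloid and pan-leukocyte list positive log2 fold changes, though none of the 14 passed over all miRNAs. The camera calls of the 2 lists (adjusted p = 9.44e-06 and 0.0392) were lost with an estimated correlation (adjusted p = 0.478 and 0.533). A lower share of epithelium as the only change would raise the miRNAs of all other cell types alike, but the leukocyte score, the mean log2 CPM of those 4 miRNAs, minus the smooth muscle score was 1.73 ± 0.44 higher in DSS than in Control on the log2 scale (standard error), which argues against it for the list as a whole. The log2 fold changes were 2.64 ± 0.68 and 2.47 ± 0.65 for the 2 arms of miR-223 but 0.68 ± 0.56 and 0.43 ± 0.46 for those of miR-142a, so this rests mostly on 1 precursor. More leukocyte RNA in DSS colon beside a loss of epithelium, and changes of these miRNAs within the cells, stay open and were not tested.

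On the first principal component DSS 2 lay at -3.04, against -14.4 and -10.3 for the other DSS libraries, and DSS_RJA 3 at -10.3, against 9.31 and 2.31 for the other DSS_RJA libraries. Exchanged labels of the 2 libraries could produce this. DSS_RJA 3 had a mean Spearman correlation across miRNAs 0.0136 higher with DSS 1 and DSS 3 than with its own group, but DSS 2 was at -0.00263, slightly closer to its own group. With the 2 libraries exchanged, DSS_RJA against DSS gave 35 calls, against 1 with the labels as given, but a variable response could give this too. An exchange and a variable response to DSS or RJA cannot be told apart, since the correlations of the 2 libraries gave different answers and no genotype or other record was used here.

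The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In DSS against Control, 1 of the 10 splits, the real one, gave as many as 17 calls, and the highest other gave 0. In DSS_RJA against DSS, 2 of the 10 gave at least the real count of 1. The highest other split, DSS 1, DSS 3 and DSS_RJA 3 against the rest, gave 35, which points to a structure of the samples that the groups do not follow. This split is the grouping with DSS 2 and DSS_RJA 3 exchanged. In DSS_RJA against Control all 10 splits gave as many as the real count of 0, and the highest other gave 0. No split can give fewer than 0 calls, so this comparison decides nothing.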
